A study of Drosophila melanogaster with 76 samples.

How the data were processed

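Whole-genome bisulfite sequencing was used to read footprints left by methyltransferases in nuclei of 2 Drosophila melanogaster cell lines. Per the labels' protocols, nuclei were treated first with M.CviPI, which methylates cytosine in GC dinucleotides, and then with SssI, which methylates cytosine in CG dinucleotides. DNA that is free of nucleosomes and other bound protein becomes methylated, and protected DNA stays unmethylated. S2 is the Schneider line, derived from embryos and resembling hemocytes. OSC is a line of ovarian somatic cells. Both lines were untreated in the samples used here.

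The deposited values are methylated fractions per dinucleotide, between 0 and 1, and per the file headers there is 1 column for each of 2 replicates of each line. Per the submitters' processing notes, Trimmomatic and Bowtie were used and the genome build was dm3, with no versions given in the sources used here. The sample titles name 2 libraries for each of the 4 columns. How these libraries were merged, and the rule by which a site was left without a value, is not given in the sources used here. All values lie on a grid of 0.01. No read counts accompany the fractions, so the depth behind each value is unknown and no interval from counting error is given. Nothing in the labels says that the 2 replicates of a line were separate cultures, so p-values measure the spread between these samples, which may be technical.

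The table holds 15403529 rows, of which 5017385 are labelled CGH, 7119956 GCH and 3266188 GCG. A GCG site can be reached by both enzymes and is listed once as a CG and once as a GC dinucleotide. In addition, 1634117 CG dinucleotides are followed 1 base later by a GC dinucleotide (CGC). Some sites labelled CGH or GCH therefore also overlap a site of the other enzyme. Values were missing at 22.2% and 22.0% of rows in the OSC replicates and at 23.6% and 23.8% in the S2 replicates. A value was present in all 4 replicates at 11312125 rows and in none at 3028208 rows. No per-sample column was left unused. Percentages of methylation below are means of fractions over rows, with every row weighted alike, so a GCG site counts in both of its rows.

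The tests were chosen before the data were examined. That plan called for a test of methylated and unmethylated read counts. As the deposited table holds fractions without coverage, its stated fallback was used instead. Non-overlapping tiles of 200 bp on the arms 2L, 2R, 3L, 3R, 4 and X were kept if at least 3 sites had values in all 4 replicates. The mean fraction per tile was put on a logit scale with an offset of 0.01, and OSC and S2 were compared by limma with a trend on mean level and Benjamini-Hochberg adjustment, calling tiles at an adjusted p under 0.05. Limma 3.58.1 ran under R 4.3.3. On simulated data, with 200 of 542801 tiles shifted, the tile test recovered 2% of tiles shifted by 0.5 on the logit scale, 10% of those shifted by 1 and 58% of those shifted by 2. In that simulation 1 of 65 calls was false. Far fewer tiles were shifted than the 112745 called in the real data, and no shift common to all tiles was simulated. These rates therefore do not carry over to the real test.

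Mean levels by context and by chromosome were compared between lines with an exact permutation test, two-sided, which with 2 replicates per line cannot go below p = 0.333. For nucleosome spacing, the correlation of methylation between sites was computed for each replicate at each distance up to 1000 bp and smoothed over 31 bp. Peak positions were refined by a parabola over 30 bp on each side. The repeat length is the slope of peak position on peak number over 4 peaks. Tested on simulated methylation at the real sites of 2L, the procedure returned 3 known repeats to within 0.08 bp. The simulation held no accessible regions, so it does not test their effect on the estimate. How fast periodicity decays was described by the height of peak 3 as a percentage of the height of peak 1, each measured from the neighbouring troughs.

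Tiles at 50% or more in both replicates of a line were called accessible in that line. Tiles at 50% or more in both replicates of one line and under 30% in both replicates of the other were called accessible in that line only. Both levels were chosen after the data had been seen. Spacing was also measured at sites over 1 kb from any tile that reached 50% in any replicate, a choice made after the first estimates had been seen. Windows of 1 Mb were first measured over all sites, gave noisy repeats, and were then limited to these sites. The decay measure, the runs of tiles, the comparisons of X with the autosomes over windows and the search for stretches without values were also chosen after the data had been seen. A profile of methylation around shared accessible tiles was computed, showed no peaks beside them and is not reported. Windows of 1 Mb were resampled 1000 times to give 95% bootstrap intervals, and windows of X were compared with autosomal windows by two-sided permutation tests with 100000 permutations, the real order included. Windows are parts of the same 4 replicates, so these intervals and tests describe variation along the genome and not between cultures. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and numba 0.67.0 were used.

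Tiles named in the text were picked by a rule fixed in advance. They are the 6 tiles with the largest difference in each direction among called tiles with at least 5 sites whose replicates did not overlap between lines. Coordinates are those of dm3, counted from 1. No annotation or genome of dm3 was used here, so tiles carry no gene names, and the planned comparisons at promoters, over gene lists and around transcription starts were not run. Alternatives covered site context, tile size, number of sites, scaling, replicates left out, replicate blocks and, for spacing, 3 estimators and 7 sets of sites. Of the 76 samples in the series, 53 amplicon, 10 short RNA and 2 whole-genome samples with a single enzyme were not analysed here. Another 3 samples, whose titles and treatment labels disagree, were assigned to no group and were not analysed here.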

Results

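Footprints of M.CviPI and SssI were measured across the genome in untreated S2 cells and in untreated ovarian somatic cells (OSC), with 2 replicates per line. A site carried a value in 11987541 and 12008756 cases in the OSC replicates and in 11763873 and 11743338 cases in the S2 replicates. Read depth per site is unknown. Across 542801 tiles of 200 bp on the chromosome arms, Pearson's r was 0.934 between the OSC replicates and 0.928 between the S2 replicates. Between lines it lay from 0.765 to 0.769. Tiles are not independent replicates.

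The first question was how much of the genome the enzymes reached in each line. The chromosome arms were methylated more in OSC, at 28.2% ± 0.624 (SD, n = 2), than in S2, at 24.8% ± 0.355 (SD, n = 2). The gap of 3.40 percentage points exceeded the spread between replicates. Both OSC replicates were above both S2 replicates in all 123 windows of 1 Mb, with differences from 1.98 to 5.88 points. At CGH sites, which report SssI apart from overlaps with GC dinucleotides, the arms stood at 25.5% ± 0.280 in OSC and 21.4% ± 0.312 in S2. At GCH sites, which report M.CviPI apart from overlaps with CG dinucleotides, they stood at 28.3% ± 0.858 and 25.5% ± 0.357. GCG sites, open to both enzymes, had the highest levels of the contexts, 31.8% ± 0.609 in OSC and 28.3% ± 0.412 in S2. The exact permutation test gave p = 0.333 in each context, the smallest value that 2 against 2 replicates allow.

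Chromosomes ranked alike in level in both lines, from the heterochromatin scaffolds up to X. The heterochromatin scaffolds were least accessible, at 21.6% ± 0.443 in OSC and 19.0% ± 0.380 in S2. Chromosome 4, small and rich in heterochromatin, lay at 26.8% ± 0.599 and 23.3% ± 0.329. The arms of chromosomes 2 and 3 lay at 28.2% ± 0.626 and 24.7% ± 0.358. X lay above these autosomal arms by 0.255 ± 0.0140 points in OSC and by 0.775 ± 0.0159 points in S2 (exact permutation p = 0.333, n = 2 per line). Mitochondrial DNA, which carries no nucleosomes, reached 89.1% ± 0.419 in OSC and 84.0% ± 0.858 in S2.

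**Figure D1:**
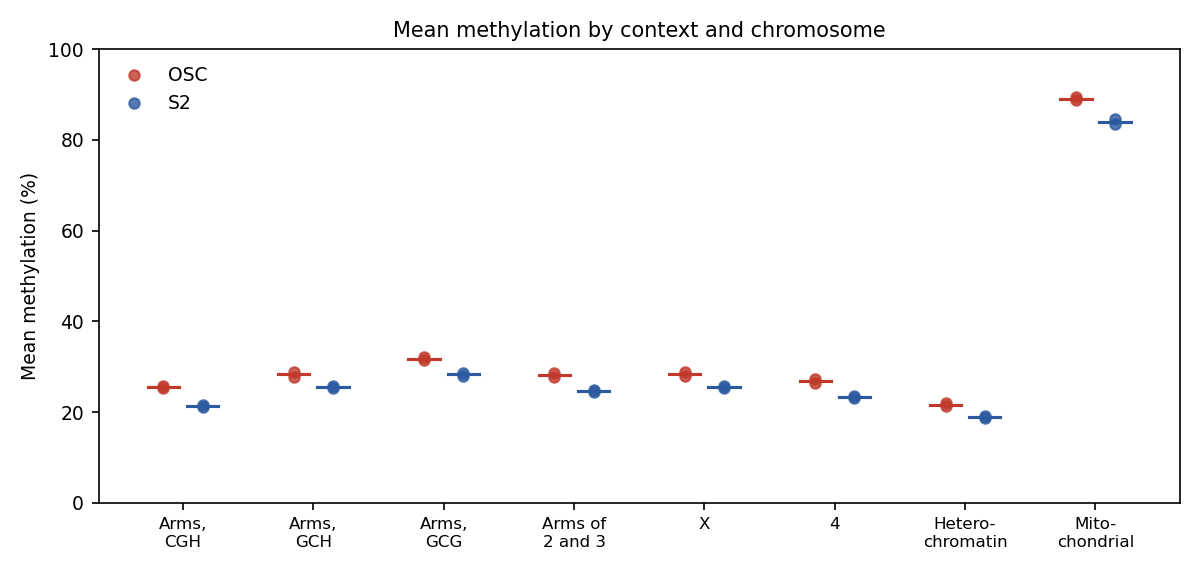
Mean methylation in percent on the vertical axis, by sequence context on the arms and by chromosome, with points for the replicates and lines for the mean of OSC in red and of S2 in blue. OSC lies above S2 in every group drawn, at 28.2% against 24.7% on the arms of chromosomes 2 and 3, and mitochondrial DNA lies far above the nuclear groups.

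The next question was where in the genome accessibility differed between the lines. Most tiles accessible in OSC were accessible in S2 too. At the level of 50% in both replicates, 17100 tiles were accessible in OSC and 15225 in S2, and 11485 were accessible in both lines, against 480 expected of independent lists. Tiles accessible in OSC and under 30% in S2 numbered 1347, and tiles accessible in S2 and under 30% in OSC numbered 755. Both levels were applied to unscaled values, which ran higher in OSC, so the balance of these counts may depend on scaling. On X, 0.214% of tested tiles were accessible in S2 only, against 0.124% on the arms of chromosomes 2 and 3. The shares accessible in OSC only were 0.237% on X and 0.25% on those autosomal arms. Over windows of 1 Mb the share accessible in S2 only was higher on X by 0.0931 points (permutation test, two-sided p = 0.00014, adjusted p = 0.00023 over 5 tests, 23 against 97 windows). The share accessible in OSC only missed the threshold (permutation test, p = 0.596, adjusted p = 0.596).

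Among tiles higher in OSC, the largest difference was on 3L at 3462001 to 3462200 (21 sites), with 93.9% ± 0.539 in OSC and 18.8% ± 0.438 in S2. It formed part of a run of 400 bp of tiles that differed by 20 points or more. On 2L, neighbouring tiles at 22024401 to 22024600 and 22024601 to 22024800 stood at 94.0% ± 2.56 and 93.2% ± 0.646 in OSC. In S2 they stood at 20.9% ± 0.0337 and 20.6% ± 0.0307. Also on 2L, tiles at 6537801 to 6538000 and 6544401 to 6544600 stood at 93.8% ± 0.890 and 84.3% ± 5.89 in OSC against 22.6% ± 0.236 and 14.0% ± 3.54 in S2. The tile on 2L at 2006401 to 2006600 stood at 92.9% ± 1.03 in OSC and 22.1% ± 0.919 in S2.

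Among tiles higher in S2, X at 13860801 to 13861000 held 87.0% ± 5.09 in S2 and 11.5% ± 0.424 in OSC, over 5 sites. The adjoining tiles on 2R at 6489401 to 6489600 and 6489601 to 6489800 stood at 86.0% ± 0.157 and 77.6% ± 1.56 in S2 and at 17.6% ± 0.786 and 16.1% ± 1.47 in OSC. They belonged to a run of 1000 bp, 6489201 to 6490200, and another run of 1000 bp higher in S2, picked after its values were seen, lay at 6488001 to 6489000. On 3L, the tile at 526601 to 526800 stood at 87.8% ± 2.67 in S2 and 22.4% ± 0.816 in OSC. Also on 3L, the tile at 13487601 to 13487800 stood at 87.2% ± 1.18 and 25.1% ± 4.92. On X, the tile at 22274001 to 22274200 stood at 81.5% ± 0.354 and 19.3% ± 0.751. Adjusted p by limma lay between 0.00025 and 0.00054 for the 12 tiles (SD, n = 2 per line).

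**Figure D2:**
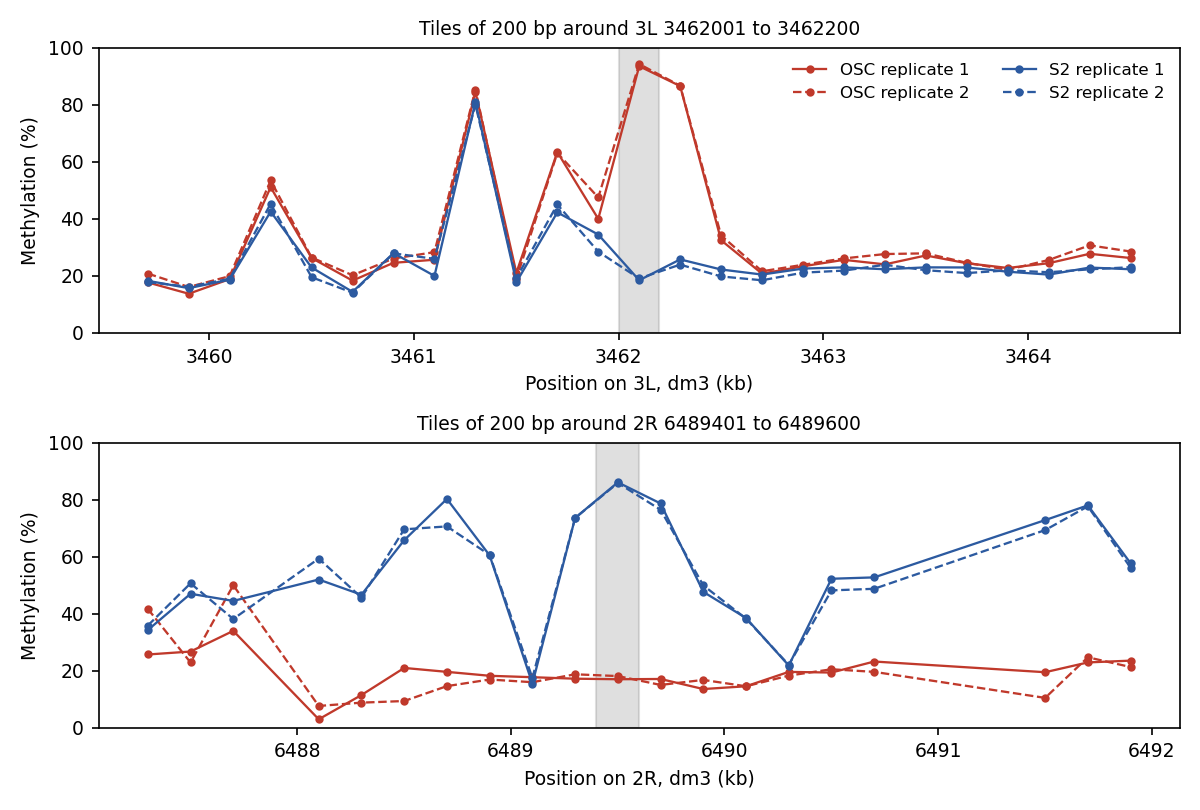
Methylation in percent of 200 bp tiles against dm3 position in kb, around the first named tile of at least 20 sites in each direction (grey), with OSC in red and S2 in blue and a line for each replicate that passes over tiles with too few sites. The shaded tile on 3L is at 93.9% in OSC and 18.8% in S2, and the shaded tile on 2R is at 17.6% in OSC and 86.0% in S2.

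By limma with Benjamini-Hochberg adjustment, 112745 of the 542801 tiles differed at an adjusted p under 0.05, 97051 higher in OSC and 15694 higher in S2. The median over tiles was 0.26 higher in OSC on a log2 scale of the odds, and with each replicate centred on its median 44653 tiles were called, 19329 higher in OSC and 25324 higher in S2. A difference of 20 points or more was reached by 5694 called tiles higher in OSC and 3501 higher in S2, of which 5514 and 3492 were also called in the same direction after centring. Counted anew on scaled values, tiles past 20 points numbered 3622 higher in OSC and 5265 higher in S2 after centring, which shifts all tiles of a replicate alike, and 5770 and 5629 after division by the mitochondrial level. Leaving out a replicate cut the count, to 3949 and 3654 without OSC replicate 1 or 2 and to 29416 and 21964 without S2 replicate 1 or 2.

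The last question was how nucleosomes were spaced. In both lines the correlation of methylation between sites rose and fell with their distance, with 4 peaks over the range measured. The repeat length over the arms was 189.3 ± 0.118 bp in OSC and 179.0 ± 0.0148 bp in S2 (SD, n = 2, exact permutation p = 0.333). This gap of 10.3 bp was smaller in each set of sites when these were split by distance from accessible tiles. At sites within 1 kb of accessible tiles the repeat was 168.6 ± 0.0610 bp in OSC and 164.7 ± 0.0455 bp in S2, a gap of 3.85 bp. At sites over 1 kb from accessible tiles the repeat was 192.7 ± 0.0366 bp in OSC and 187.9 ± 0.0689 bp in S2, a gap of 4.80 bp. At these more distant sites, the OSC mean exceeded the S2 mean in 121 of 121 windows of 1 Mb, by a median of 4.85 bp, and both OSC replicates exceeded both S2 replicates in 119 of them. Bootstrap over windows gave 4.86 bp (4.54 to 5.15) for the autosomal arms and 4.77 bp (4.03 to 5.58) for X.

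X stood apart from the autosomes in S2. Over all sites its repeat there was 171.4 ± 0.00586 bp, against 179.9 ± 0.0926 bp on the autosomal arms, while in OSC both were 189.3 bp. The difference in S2 rested largely on peak 4. In S2 replicate 1, peak 3 lay at 535.0 bp on X and 541.7 bp on the autosomal arms, and peak 4 at 696.6 and 727.3 bp. In S2 replicate 2, peak 3 lay at 535.6 and 541.6 bp, and peak 4 at 695.6 and 726.8 bp. This gap in S2 of −8.54 bp was −4.81 bp at GC sites, −3.31 bp without GCG and CGC sites, −4.40 bp by damped cosine, −1.31 bp with a running mean taken off without GCG and CGC sites, and −4.49 bp within 1 kb of accessible tiles. At sites over 1 kb from accessible tiles the repeats in S2 were 187.4 ± 0.240 and 188.0 ± 0.0460 bp, a gap of −0.518 bp (bootstrap at sites with values in all 4 replicates, −0.418 bp, −1.34 to 0.44). X was shorter in OSC too when sites were split in this way. Its gap in OSC was −2.85 bp within 1 kb of accessible tiles and −0.575 bp at the more distant sites. The strength of the pattern still differed at those sites. The height of peak 3 was 34.4% ± 0.709 of peak 1 on X in S2, against 41.3% ± 0.171 on the autosomal arms. In OSC it was 44.5% ± 0.167 on X and 44.8% ± 0.561 on the autosomal arms. Within 1 kb of accessible tiles the lines stood the other way round, with 39.7% ± 0.393 in OSC and 52.8% ± 1.53 in S2 on X, and 42.0% ± 0.435 and 53.1% ± 0.226 on the autosomal arms. Over windows of 1 Mb at the more distant sites, OSC exceeded S2 in this measure by 9.84 ± 4.28 points on X and by 3.05 ± 3.57 points on the autosomal arms (SD over windows, permutation test, two-sided p = 2e-05, the smallest these permutations can give, adjusted p = 4e-05 over 2 tests). With pairs of sites taken across replicates instead of within one, the shortfall of X in S2 was smaller, −2.94 points (−5.38 to −0.46) in place of −6.89 (−9.36 to −4.23), and its difference from the shortfall in OSC was −2.69 points (−4.73 to −0.83) in place of −6.77 (−8.68 to −5.01).

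**Figure D3:**
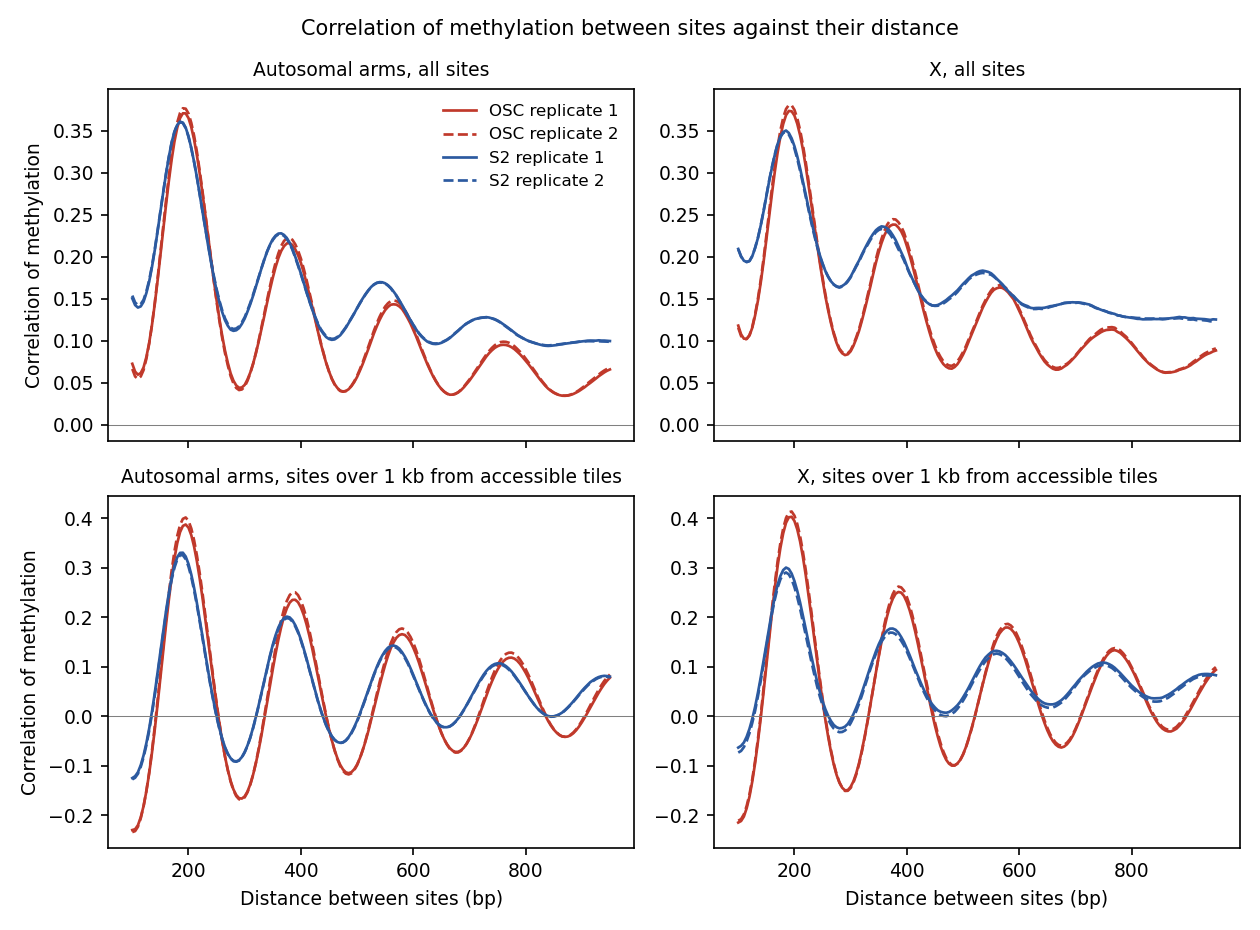
Correlation of methylation between sites on the vertical axis against their distance in bp, for the autosomal arms and X over all sites (upper panels) and over sites more than 1 kb from accessible tiles (lower panels), with a line per replicate of OSC (red) and S2 (blue). The OSC peaks lie at larger distances, a repeat on the autosomal arms of 189.3 against 179.9 bp over all sites and of 192.8 against 188.0 bp in the lower panels, drawn from sites with values in all 4 replicates.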

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

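The tests of explanations, the resampling of windows and the comparisons over windows in this part were chosen after the results had been seen.

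Over all sites, the height of peak 3 over peak 1 on X minus that on the autosomal arms was 0.748 points in OSC, above 0 in both replicates, and −5.51 points in S2, below 0 in both, a difference of −6.26 points (exact permutation p = 0.333, the smallest that 2 against 2 replicates allow, so the test could not pass). Over windows of 1 Mb at sites more than 1 kb from accessible tiles, the difference of OSC minus S2 was larger on X by 6.79 points (permutation test, p = 2e-05, the smallest these permutations can give, adjusted p = 4e-05). By bootstrap over windows the same contrast, as S2 minus OSC, was −6.77 points (−8.68 to −5.01) within replicates and −2.69 points (−4.73 to −0.83) with pairs across replicates.

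Nearby accessible regions may explain the shorter repeat on X in S2, −8.54 bp over all sites and −0.418 bp (−1.34 to 0.44) more than 1 kb from them. But the gap also depended on sites and estimator. It was −3.31 bp without GCG and CGC sites, −4.40 bp by damped cosine and −1.31 bp with a running mean taken off without GCG and CGC sites. Over all sites it rested largely on the position of peak 4. In OSC the repeat on X was shorter too within 1 kb of accessible tiles, by −2.85 bp against −4.49 bp in S2. Further away the gaps were −0.575 bp in OSC and −0.518 bp in S2. The decay on X in S2 differed by −5.51 points over all sites and by −0.314 points within 1 kb of accessible tiles. At the more distant sites it still differed, by −6.89 points (−9.36 to −4.23). The difference did not shrink away from accessible tiles, so those within 1 kb do not account for it at the more distant sites. Less accessible stretches and tiles with too few sites were not left out there, so their part cannot be told. In OSC the same sites gave −0.118 points (−2.01 to 1.82), so a sequence effect of X alike in both lines does not account for the decay. A sequence effect that shows only in S2 is not excluded. Reads that cover both sites of a pair could carry most of the decay difference, since pairs taken across replicates gave −2.94 points (−5.38 to −0.46), which excludes them only as the whole of it. A less regular array of nucleosomes on X in S2, a male line with dosage compensation of X, stays open as a hypothesis, as does the copy number of X, and neither was tested.

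Tiles higher in S2 formed a larger share of the tiles in windows of X than in windows of the autosomal arms. The excess was 1.51 points for tiles called higher in S2 (p = 2e-05, adjusted p = 5e-05) and 2.07 points after centring of the replicates (p = 2e-05, adjusted p = 5e-05), by permutation tests. For tiles accessible in S2 only it was 0.0931 points (permutation test, p = 0.00014, adjusted p = 0.00023). Tiles called higher in OSC after centring were on average 3.96% of the tiles in windows of X and 3.43% of those in autosomal windows, an excess of 0.527 points that missed the threshold (permutation test, p = 0.106, adjusted p = 0.132), and the excesses of the lines were not tested against each other.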

How the results depend on the processing

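Alternatives other than those planned were chosen after seeing the data. They were a smaller offset, mitochondrial scaling, other levels of accessibility, 20 points and sites without GCG and CGC overlap. Sites shared by all replicates, distance from accessible tiles, other estimators and pairs across replicates were also among them. The comparison of X with the autosomes in repeat length and decay was chosen after seeing the data too, while that in level was planned. OSC stayed above S2 in level and in repeat length under each setting run. All 12 named tiles kept direction in the 153 values computed, with a smallest difference of 53.6 points. These tiles were picked as the largest differences in the same values, so a change of direction was unlikely from the start and this is no independent support. The tile on X at 13860801 to 13861000, with 5 sites, had no value at CG sites alone or with at least 6 sites. The tile count of 112745 moved to 44653 with centring, 47570 after division by the mitochondrial level, 72553 of 114745 with tiles of 1000 bp, 45239 with 10 points and 9195 with 20 points. Leaving out a replicate gave 3654 to 29416 tiles, where the lone replicate is assumed to vary like the other groups and fewer degrees of freedom remain. With replicate number as a block the count was 98857, and the numbers did not pair the samples (r = 0.0022 between the lines' replicate differences). The level gap of 3.40 points was 4.17 at CG sites, 2.84 at GC sites, and 2.95 to 3.84 with a replicate left out. The excess of X in level, 0.520 points larger in S2, was 0.567 at GC sites, 0.467 at CG sites and 0.484 at sites shared by all replicates. The repeat gap of 10.3 bp was 9.85 at GC sites, 9.11 at CG sites, 17.9 on X, 9.33 on the autosomal arms, 10.2 with a running mean taken off, 9.65 by damped cosine, 10.7 at shared sites, 8.80 without GCG and CGC sites, 4.80 at sites over 1 kb from accessible tiles, 3.85 within 1 kb and 4.88 across replicates far from accessible tiles. The repeat on X minus autosomes in S2, −8.54 bp, was −4.81 at GC sites, −7.72 at CG sites, −8.99 at shared sites, −3.31 without GCG and CGC sites, −0.518 far from and −4.49 near accessible tiles, −6.07 with a running mean taken off, −1.31 with a running mean taken off at sites without GCG and CGC overlap, −4.40 by damped cosine and −0.835 across replicates far from accessible tiles. The decay measure, −5.51 points, was −6.86 at GC sites, −6.31 at CG sites, −4.12 without GCG and CGC sites, −6.97 far from and −0.314 near accessible tiles and −2.94 across replicates far from them. The cause of these shifts was not tested beyond the distance from accessible tiles. Shared accessible tiles numbered 17942 at a level of 40% and 7316 at 60%. Coverage minimums, a coverage-weighted mean, a count test, single libraries and all promoter, gene list and transcription start settings were not run. Unknown depth limits all values per site.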

Other observations

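The tests and searches in this part were chosen after the data had been seen.

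Differences of 20 points or more between the lines came mostly in short stretches. The smaller gap in level was not of this kind, as OSC lay above S2 in all 123 windows of 1 Mb. Accessible stretches were short in general. With adjoining accessible tiles joined, 7121 of 11231 regions in OSC and 7074 of 10485 in S2 were a single tile. Called tiles that differed by 20 points or more joined into 4033 runs higher in OSC, 2849 of them a single tile, and 2557 runs higher in S2, 1838 of them a single tile. The runs hold 5694 tiles higher in OSC and 3501 higher in S2, and a new count of tiles past 20 points on centred values gave 3622 and 5265, so the balance between the lines depends on scaling. The longest run higher in OSC covered 1800 bp on 3L at 15184201 to 15186000, with 61.3% and 63.6% in the OSC replicates and 28.7% and 25.2% in the S2 replicates. A run of 1400 bp on 2R at 3319001 to 3320400 stood at 80.1% and 81.0% in OSC and 23.3% and 25.4% in S2. The longest run higher in S2 covered 1200 bp on X at 7527401 to 7528600, with 69.4% and 69.7% in S2 and 24.1% and 25.6% in OSC. These runs were picked after their values had been seen.

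Among windows of 100 kb, the one with most tiles accessible in OSC only was on 3R at 18000001 to 18100000, with 12 tiles against a mean of 1.12 per window. The one with most tiles accessible in S2 only was on 2R at 6400001 to 6500000, with 13 tiles against a mean of 0.633. It holds the neighbouring named tiles of 2R, and most of its tiles accessible in S2 only lay in 1 stretch from 6488001 to 6492000. In 1000 random spreads of the tiles over 1193 windows the highest counts were 9 for OSC and 8 for S2, but neighbouring tiles are not independent. The spreads placed each tile on its own, so they cannot tell a cluster across a window from 1 stretch of nearby tiles.

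OSC had a higher level than S2 on the arms, but incomplete bisulfite conversion in OSC would leave little difference in tiles that are mostly methylated. In the 2238 tiles between 80% and 90% it was 6.01 points, above the 3.40 points over the arms, so incomplete conversion does not account for the difference in those tiles. Most tiles lay lower, with 3.41 points in the 372191 tiles between 20% and 30%. The gap was 2.03 points in the 89136 tiles between 10% and 20% and 0.516 points in the 538 tiles under 10%. Incomplete conversion would add most in such closed tiles, so these values argue against it as the main reason. A part from incomplete conversion is not excluded. Weaker M.CviPI treatment of the S2 preparations would lower mitochondrial GCH sites in S2 too. There OSC exceeded S2 by 5.28 points (4.13 to 6.49, bootstrap over 88 sites). The replicates stood at 91.3% and 91.5% in OSC and at 87.2% and 85.1% in S2. Intervals over mitochondrial sites describe variation between sites and not between preparations. Weaker SssI treatment cannot be told apart from its absence, since 39 mitochondrial CGH sites gave 0.282 points, with an interval (−5.28 to 4.23) that holds 0 and also the 4.21 points of the arms at sites with values in all 4 replicates. As a ratio of rates of S2 over OSC, which assumes that all sites react alike, the CGH sites gave 0.991 (0.865 to 1.18), above the 0.814 of the arms, which goes against weaker SssI but rests on that assumption, and the GCH sites gave 0.805 (0.767 to 0.842), below the 0.881 of the arms. On that scale the GCH sites gave no sign of more open chromatin in OSC, while the CGH sites did, so the enzymes disagree. More open chromatin in OSC is thus not settled, as the scale rests on its assumption and preparation and line are confounded.

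On X from 2691001 to 2818000 of dm3, a span found by a search for bins of 1000 bp with at least 90% of sites missing in both replicates of OSC and at most 10% in those of S2, each OSC replicate lacked a value at 99.8% of 11894 sites, against 23.7% and 23.8% in the S2 replicates. Reads that cannot be placed in repeats are unlikely as the whole reason, since in the bins of the span that the search did not select 54.6% of 6655 sites had values in both S2 replicates, and 3 of those 3636 sites had one in OSC, but they may account for part, as 41.2% and 41.0% of the sites in these bins lacked a value in the S2 replicates. Low depth of the OSC libraries is unlikely too, since at most 5.23% of sites in the flanks of 100 kb lacked a value in an OSC replicate. A deletion in OSC and sequence that differs from the reference stay open and were not tested.

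The longest stretch without values in S2 alone was on 2R at 1152001 to 1171000, where both S2 replicates lacked a value at 100% of 1757 sites, against 4.38% and 3.59% in the OSC replicates.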
